A study of Mus musculus with 2 samples.

How the data were processed

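MicroRNA sequencing had been carried out on forebrain dissected from mouse embryos of the B6NCrl strain at embryonic day 13.5, with tissue of both sexes pooled. MicroRNAs are short regulatory RNAs cut from hairpin precursors, and per the labels the libraries were limited to RNA shorter than 30 nucleotides. There were 2 libraries, which the labels name as biological replicates 1 and 2 of 1 group. They carry separate biosample identifiers and the same donor identifier, and the labels do not say which embryos went into which pool. The spread between them is therefore the spread of these 2 libraries, which may in part be technical.

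The deposited files hold whole-number counts of reads per gene, 1 table per library, with replicates not pooled. The genome build mm10 and the GENCODE M4 annotation were taken from the read-me texts deposited with the tables. The aligner and its settings are not given in the sources used here. Each table has 3 columns of counts, for reads on either strand, on the strand of the gene and on the opposite strand, and 4 summary rows for unmapped, multi-mapped, unassigned and ambiguous reads. In each library the deposited columns, summary rows included, have the same total. Because multi-mapped reads stand in a row of their own, a read that fits several copies of a microRNA was taken to add no count to any of them. The counting tool is not given in the sources used here, so counts of genes with copies are uncertain. Counts on the strand of the gene were the main measurement. The summary rows were left out of library sizes and tests. In replicate 1 they held 16.7% unmapped, 40.6% multi-mapped and 3.99% unassigned reads, and in replicate 2 15.0%, 43.9% and 3.71%. Ambiguous reads numbered 0 in both libraries.

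Each table lists 1973 microRNA genes by Ensembl identifier. Symbols, positions and host genes were taken from GENCODE M21, a later release on the same build (GRCm38, also called mm10). Of the identifiers, 1894 matched, and the 79 without a match held 1 count in replicate 1 and 4 in replicate 2. A gene was said to have a copy when another annotated microRNA transcript outside its own locus shared an exact stretch of at least 20 nucleotides in either orientation. This search covered annotated microRNA transcripts and not the genome. By this measure 929 genes had a copy, 82 of them among the detected genes.

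CPM values, counts relative to 1000000 gene counts of the library, were computed here from the deposited counts. They compare reads, and how evenly different microRNAs were captured in the libraries was not measured. A bias shared by both libraries would not show in their SD, so ranks, shares and ranges between genes describe reads counted. A gene was called detected with at least 10 counts in each library. A count of 0 allows up to 3 counts, which is 0.729 CPM in replicate 1 and 0.767 CPM in replicate 2. Shares of single libraries have 95% Wilson intervals. Ratios between the libraries are log2 of replicate 2 over replicate 1 after TMM normalization with edgeR 4.0.16 in R 4.3.3, with a prior count of 0.5, and have exact (Clopper-Pearson) 95% intervals. Intervals, limits and binomial tests cover counting error only, since reads amplified by PCR are not independent molecules. The common dispersion was estimated by edgeR with an intercept-only design over the detected genes.

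With 1 group there is no comparison between conditions, and no test between groups was made. The libraries themselves were compared gene by gene with a two-sided exact binomial test on counts with TMM library sizes. Benjamini-Hochberg adjustment ran over genes with at least 10 counts in the libraries together, and genes were called at an adjusted p under 0.05 and an absolute log2 ratio over 1. This test compares the libraries and not conditions. The tables were not copies of 1 library, since a chi-square of their counts over detected genes was 32540 on 376 degrees of freedom.

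A total of 17 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. For each list the share of gene counts was computed. Its median log2(CPM + 1) was placed among 10000 random lists drawn from the whole table. For lists with at least 3 detected genes, the median log2 ratio between the libraries was placed among 10000 random lists matched on mean CPM, drawn from the 20 genes nearest in mean CPM to each member. These percentiles describe the libraries and are not tests. Named genes were the 25 with the highest mean CPM, up to 4 leading detected members of each list (or the highest member where none was detected), up to 10 called genes with the largest absolute log2 ratio and at least 50 counts in a library, and genes in the closing section. Other genes named were chosen after their values were seen.

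The exact binomial test and the matched lists were tested on simulated data. In a simulation of replicate 2 over replicate 1 with 465 genes tested, all of the changed genes were called (100% of 100 genes at a log2 change of 1.5 and 100% of 100 genes at -3), as were 1.13% of unchanged genes. A simulated list shifted by -0.5 lay at percentile 0.02, and 3 of 100 unshifted lists lay outside the central 95% of random lists. The changed genes and the simulated lists were drawn from genes with a mean CPM of at least 10. The simulated counts held counting error only, with known library sizes, and the simulated list values were independent between genes. These checks therefore do not cover spread between replicates or lists of clustered genes. They also do not cover recovery of changes in genes below 10 CPM or of changes nearer the cutoff. Alternatives were reads on either strand, other detection floors and count filters, another pseudocount (10 CPM in place of 1 CPM), DESeq2 1.42.0 size factors, library totals, an edgeR exact test, other denominators, genes with copies left out, and each replicate left out. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.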

Results

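The microRNA content of the mouse forebrain at embryonic day 13.5, during the period of neurogenesis, was measured by small RNA sequencing in 2 biological replicates of 1 group. Replicate 1 held 10631040 reads, of which 4117752 (38.7%) were counted on microRNA genes. Replicate 2 held 10452225 reads with 3908953 (37.4%) counted. At this depth 1 count equals 0.243 CPM in replicate 1 and 0.256 CPM in replicate 2. Values are given as mean ± SD with n = 2 libraries unless stated otherwise.

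Among reads counted on genes, Mir99a was the most abundant microRNA gene, at 195743 ± 1983 CPM, which was 19.6% ± 0.198 of all gene counts. Multi-mapped reads, 40.6% of all reads in replicate 1 and 43.9% in replicate 2, stand outside this ranking. Genes with copies may therefore rank too low in it. The gene (ENSMUSG00000065530.1) lies in an intron of Mir99ahg on chromosome 16 at 77598936 to 77599000 (GRCm38). Mirlet7g, in an intron of Wdr82, followed at 58085 ± 4019 CPM, and Mir335, in an intron of the imprinted gene Mest, at 52295 ± 551 CPM. Mir17 stood at 48988 ± 625 CPM and Mir130a at 33916 ± 1242 CPM. The Mir99a relatives Mir99b, in an intron of Spaca6, and Mir100 reached 29287 ± 2645 and 26181 ± 2444 CPM. Mir149, in an intron of the glypican gene Gpc1, stood at 25057 ± 2465 CPM. The order of the leading genes Mir99a and Mirlet7g was the same in both libraries, and the gap between them was far larger than the replicate SD. Mirlet7i (31780 ± 4646 CPM) and Mir130a differed by less than the replicate SD of Mirlet7i.

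The profile of reads counted on genes was concentrated in few genes. The 10 most abundant genes held 51.7% of the gene counts in replicate 1 (95% Wilson interval 51.6 to 51.7) and 53.3% in replicate 2 (53.2 to 53.3), or 52.5% ± 1.15, and all 10 were shared by the libraries. The 25 most abundant held 72.6% ± 1.35, with 23 shared. In replicate 1, 62 genes made up 90% of the counts, and in replicate 2, 58 genes. A total of 377 genes were detected, 91 of them over 1000 CPM and 19 over 10000 CPM, while 1253 genes had 0 counts in both libraries. With a floor of 1 count in each library the number of detected genes was 602. Relative to all reads, multi-mapped and unmapped ones included, the 10 leading genes held 19.97%, and every list share below was lower by more than 1.5 times.

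**Figure D1:**
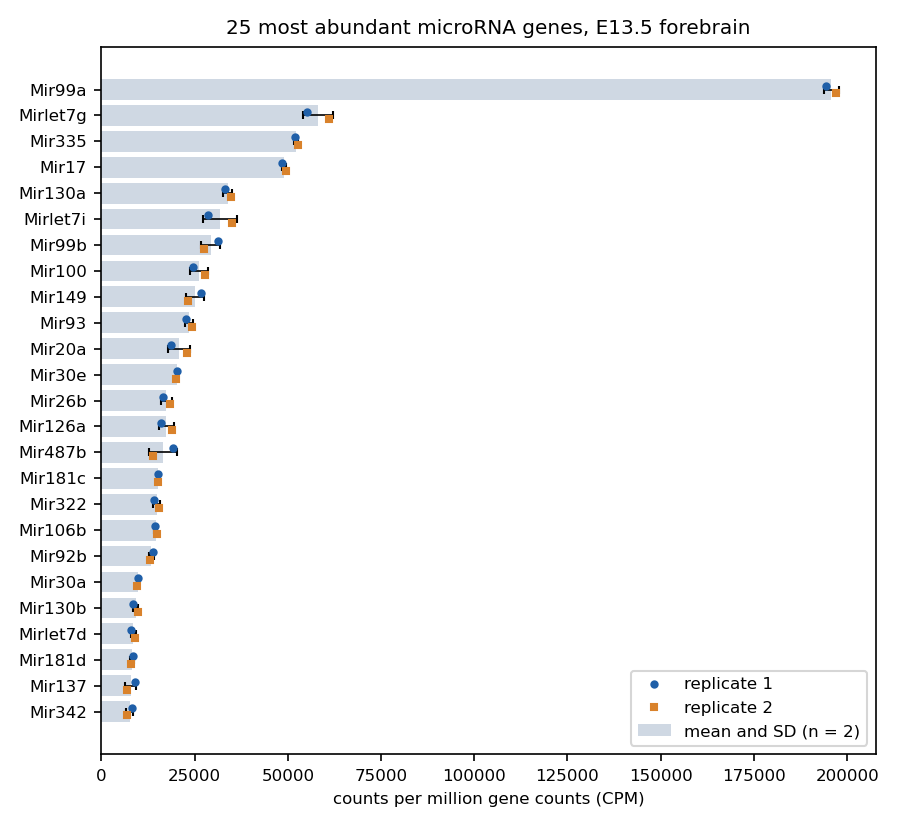
CPM (x axis) of the 25 most abundant microRNA genes (y axis), with circles for replicate 1, squares for replicate 2, and bars with error bars for the mean and SD of the 2 libraries. Mir99a, at 195743 CPM, stands apart from Mirlet7g at 58085 CPM and from the rest.

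The let-7 family, whose mature forms rise as progenitors differentiate, held 11.0% ± 1.06 of the gene counts, with 10 of 10 measured members detected. Reads of Mirlet7e and Mirlet7f-1, counted only as opposite-strand reads of other genes, are in neither this share nor the order below. Mirlet7g and Mirlet7i made up most of it, followed by Mirlet7d at 8523 ± 716 CPM and Mir98, in an intron of Huwe1, at 5843 ± 775 CPM. Members with copies stood lower, such as Mirlet7a-1 at 169 ± 4.44 CPM. The median log2(CPM + 1) of the list was 11.2, at percentile 100 of random lists from the table. This percentile says little, since 1253 of the 1973 genes had 0 counts in both libraries. Even the striated muscle list stood at percentile 93.2. In the ratio between the libraries all 10 members were higher in replicate 2, and 7 of them passed the exact binomial test at an adjusted p under 0.05 (7 adjusted over the list alone). Their median log2 ratio was 0.28, at percentile 99.9 of matched random lists. With library totals in place of TMM, 9 of the 10 were higher and the median was 0.17.

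The Mir17 cluster and its paralogs on chromosomes X and 5, which are associated with proliferation, held 12.3% ± 0.458 of the counts, and 15 of 15 members were detected. Mir17 led, followed by Mir93 in Mcm7 at 23411 ± 1109 CPM, Mir20a at 20816 ± 2872 CPM and Mir106b in an intron of Mcm7 at 14610 ± 435 CPM. Members of 1 cluster differed widely in reads counted, which need not equal differences in the amount of RNA. In the chromosome 14 cluster (115043671 to 115044506, in Mir17hg), Mir17 stood 2135-fold above Mir19b-1, which had 22.9 ± 1.20 CPM. Mir19b-1 has a copy in the paralogous cluster. With genes that have copies left out the range was 527-fold. The chromosome 5 cluster spanned 31.3-fold, and the chromosome X cluster 180-fold, from Mir106a at 1211 ± 172 CPM to Mir19b-2 at 6.74 ± 0.600 CPM. Without genes that have copies, Mir19b-2 among them, the latter was 13.3-fold, down to Mir18b at 91.2 ± 21.1 CPM. Between the libraries 11 members were higher in replicate 2 and 4 lower, 6 and 3 of them past the exact test (9 in all, and 10 adjusted over the list alone). The median log2 ratio was 0.13, at percentile 91.7, and with library totals it was 0.03, with 8 higher and 7 lower.

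The imprinted Dlk1-Dio3 cluster held 6.71% ± 0.994 of the counts, with 42 of 46 measured members detected. Among members counted on their own strand, the leading ones were Mir487b at 16517 ± 3870 CPM, Mir369 at 7177 ± 446 CPM, Mir127 at 5942 ± 336 CPM and Mir411 at 5271 ± 196 CPM. Reads of Mir409, Mir376a, Mir299a and Mir380, counted only as opposite-strand reads of other genes, are in neither this order nor the share. Across the region (chromosome 12, 109563692 to 109747960) the detected range was 4548-fold, down to Mir1197 at 3.63 CPM. With genes that have copies left out, Mir487b and Mir411 among them, the share was 4.89% and the range 1976-fold. The cluster was lower in replicate 2, with a median log2 ratio of -0.20 at percentile 0.03 of matched random lists. Of the detected members 36 were lower and 6 higher, and 26 lower and 1 higher passed the exact test (27 in all, and 27 adjusted over the list alone). Mir487b had 79279 counts in replicate 1 and 53867 in replicate 2, a log2 ratio of -0.37, while Mir127 and Mir369 did not pass, at -0.01 and -0.02. With library totals 39 were lower and 3 higher.

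**Figure D2:**
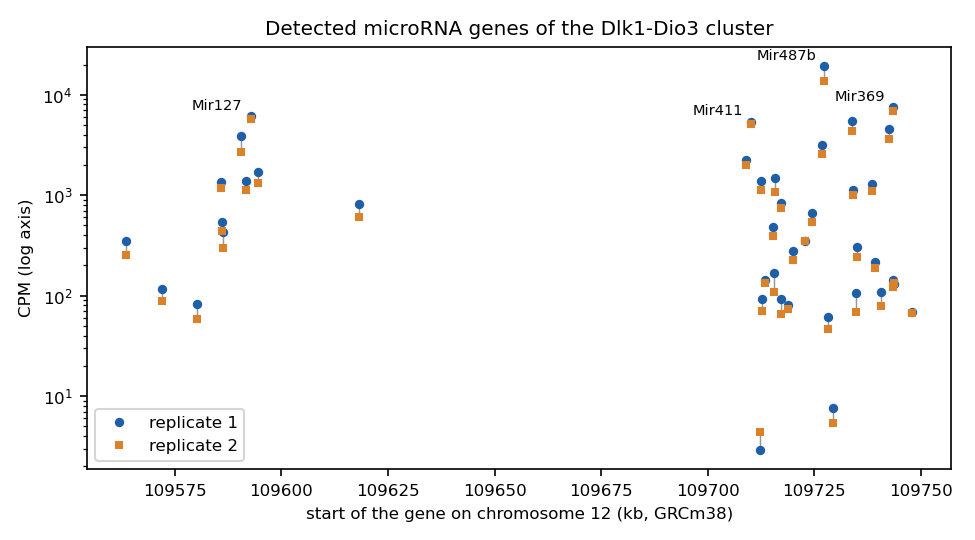
CPM (y axis, log scale) of the 42 detected microRNA genes of the Dlk1-Dio3 cluster against the start of each gene on chromosome 12 in kb (GRCm38), with circles for replicate 1, squares for replicate 2 and a line joining both. The genes run from Mir1197 at 3.63 CPM to Mir487b at 16517 CPM.

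MicroRNAs enriched in neural progenitors or neurons held 3.27% ± 0.297 of the counts, and 19 of 21 measured members were detected. Reads of Mir9-1, counted only as opposite-strand reads of another gene, are not in this share. Mir92b led at 13430 ± 660 CPM, followed by Mir137 at 7852 ± 1559 CPM, Mir125b-1 at 2149 ± 221 CPM and Mir153, in an intron of Ptprn2, at 2027 ± 63.0 CPM. The log2 ratio of replicate 2 over replicate 1 was -0.30 for Mir137 and 0.01 for Mir92b. The genes of miR-124, the microRNA that characterises neurons, had few counts: 8 and 6 for Mir124a-1, 20 and 19 for Mir124a-2, and 3 and 3 for Mir124a-3. Of the 21 members 15 have a copy, and the tables hold multi-mapped reads in a row of their own. The median CPM was 327 for members with a copy and 1779 for the 6 without. The list's median log2 ratio was 0.01, at percentile 50.9. With TMM 9 members were lower and 10 higher in replicate 2, and with library totals 16 and 3, with a median of -0.10. Past the exact test, 7 were lower and 2 higher (9 in all, and 9 adjusted over the list alone).

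Against other lists, the neural share was higher in both libraries, with no overlap of their ranges, for 12 of 15 lists compared, and lower for 3, the let-7 family, the Mir17 cluster and paralogs, and the Dlk1-Dio3 cluster. A share sums over members, and the neural list had 21 measured members, more than each of the 12 lists it exceeded (1 for the endothelial list). Of the neural members 15 have a copy, against 5 of 10 in the let-7, 4 of 15 in the Mir17 and 4 of 46 in the Dlk1-Dio3 list. Multi-mapped reads left uncounted may therefore bear on the 3 lower results. The comparison does not measure tissue composition. With 2 libraries no permutation test can reach the threshold, and none was made. The smallest excess was over the endothelial list, at a ratio of 1.90 ± 0.384. It was 3.96 ± 0.579 over the choroid plexus list and 91.1 ± 18.5 over the Hox-embedded list.

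Lists of other cell types and regions held lower summed shares than the neural list. Endothelial Mir126a, in Egfl7, reached 17435 ± 1970 CPM (1.74% ± 0.197), with a log2 ratio of 0.34. As a single gene it stood above the leading neural gene, Mir92b, at 13430 ± 660 CPM. The choroid plexus and multiciliated list held 0.840% ± 0.198, with 7 of 7 members detected, led by Mir449a in an intron of Cdc20b (6352 ± 1409 CPM), Mir204 in an intron of Trpm3 (1339 ± 325 CPM) and Mir34c (663 ± 233 CPM). Mural and mesenchymal microRNAs held 0.692% ± 0.0326, of which Mir143 had 3525 ± 628 and Mir140 3032 ± 196 CPM. The epithelial list held 0.164% ± 0.00618, and Mir203 made up most of it at 1376 ± 46.8 CPM. The pluripotency list held 0.102% ± 0.0278, mostly Mir302a (381 ± 107 CPM), Mir302d (345 ± 86.5 CPM) and Mir302b (241 ± 73.9 CPM). With genes that have copies left out, Mir302a and Mir302b among them, that share was 0.0429%. The oligodendrocyte list held 0.0778% ± 0.00498, or 0.0198% without Mir219a-1 (551 ± 52.1 CPM) and Mir219a-2, which have copies, leaving Mir338 (182 ± 1.40 CPM).

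Microglial, blood, muscle, liver and posterior lists were near the bottom of the range. The leukocyte and microglia list held 0.0298% ± 0.000517, led by Mir155 at 163 ± 9.33 CPM and Mir223 at 95.8 ± 9.16 CPM. Mir142 is not in that share: 170 ± 2.04 reads relative to 1000000 gene counts fell opposite to Mir142b, more than the CPM of Mir155, and would raise the share by more than 1.5 times. The Hox-embedded list, of genes expressed in hindbrain, spinal cord and trunk, held 0.0370% ± 0.0108, led by Mir10a (216 ± 66.0 CPM) and Mir10b (119 ± 36.5 CPM). The sensory organ list (Mir182, Mir183 and Mir96) held 0.0382% in replicate 1 and 0.0186% in replicate 2, a mean of 0.0284% ± 0.0139. The liver and gut list held 0.0211% ± 0.000597, with Mir122 at 56.0 ± 4.64 CPM, and the erythroid list 0.0123% ± 0.00517. The striated muscle list held 0.00497% ± 0.000839, led by Mir208b in an intron of Myh7 at 35.8 ± 2.91 CPM. Its members Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b, which have copies, had 0 counts in both libraries, and Mir1a-2 was not measured. Reads of these genes may be among the multi-mapped ones, so the share and the order may reflect the counting. The testis list of 12 X-linked genes had 0 counts in replicate 1 and 3 in replicate 2, of which Mir871 had 2. Expression of that list was not detectable at this depth.

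**Figure D3:**
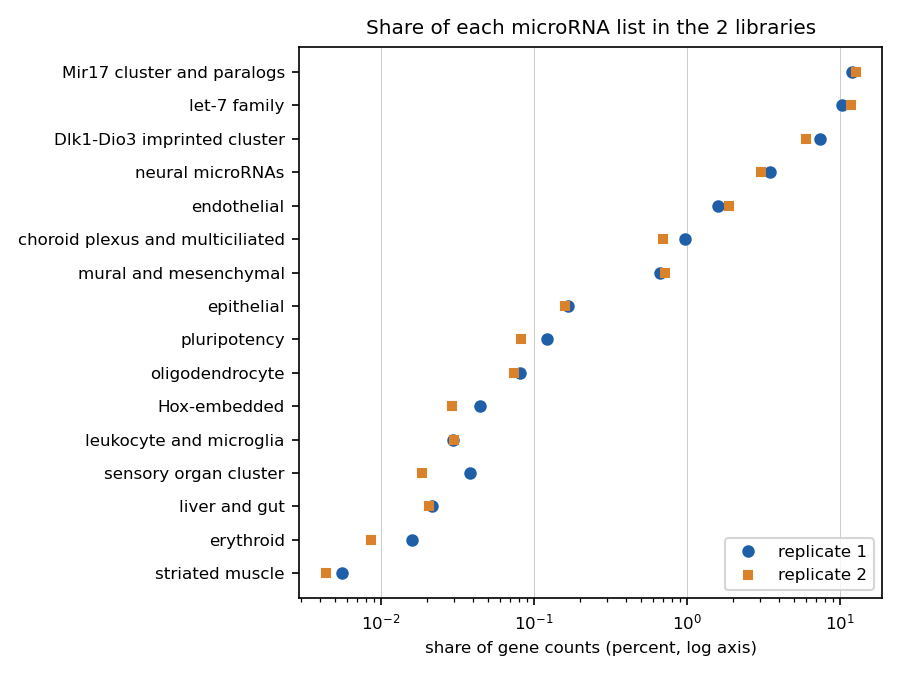
Share of gene counts in percent (x axis, log scale) of the 16 lists with detected genes (y axis), with circles for replicate 1 and squares for replicate 2. Shares run from 0.00497% for striated muscle to 12.3% for the Mir17 cluster and paralogs.

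The libraries were close in most genes, and some groups of microRNAs stood apart. Across the 377 detected genes, which are not independent replicates, the Spearman correlation of log2(CPM + 1) was 0.993 and the Pearson correlation 0.995. The biological coefficient of variation was 14.3%, and 334 genes (88.6%) lay within 1.5-fold. TMM set the median log2 ratio of detected genes at 0.03, and library totals moved ratios by -0.11, so that directions near 0 depend on the scaling. Of 475 genes tested, 185 passed an adjusted p under 0.05 in the exact binomial test, 86 higher and 99 lower in replicate 2. With DESeq2 size factors these were 67 and 118, and with library totals 54 and 141. With the log2 ratio over 1 as well, 16 genes were called, 2 higher and 14 lower. An edgeR exact test with the estimated dispersion called 1 gene, with 31 of 475 at an unadjusted p under 0.05. That dispersion was estimated from the difference between these same libraries, so few calls follow by construction. With at least 50 counts in each library the binomial test called 2. The binomial test covers counting error only, so passing it does not place a ratio beyond the replicate spread.

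The called genes with at least 50 counts in a library were Mir451a, an erythroid microRNA, Mir96 of sensory cells, and Mir3059 in an intron of Mgat4c. Mir451a had 507 counts in replicate 1 and 134 in replicate 2 (log2 ratio -1.73, exact binomial adjusted p = 3.25e-41). Its neighbour Mir144 went the other way, with 109 and 164 counts (0.77, adjusted p = 5.24e-05). Mir96 had 235 and 90 counts (-1.20, adjusted p = 1.27e-11), and Mir3059 had 54 and 23 (-1.03, adjusted p = 0.00903).

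Besides the let-7 and Dlk1-Dio3 lists, 4 of the remaining lists lay outside the central 95% of matched random lists, which draw genes singly although members of the Dlk1-Dio3, pluripotency, sensory organ and choroid plexus lists are clustered (the last holds 7 genes in 4 loci). The choroid plexus and multiciliated list had a median log2 ratio of -0.39 (percentile 0.07), with 6 of 7 members lower in replicate 2 and 4 past the exact test. The sensory organ list stood at -0.94 (percentile 0), with 3 of 3 lower and past the test. The pluripotency list stood at -0.41 (percentile 0.61), with 6 of 7 lower and 4 past the test. These counts were the same when adjusted over the list alone. The leukocyte and microglia list stood at 0.32 (percentile 98.0), with 3 of 4 members higher and 1, Mir223, past the test. With library totals 0 of its members passed (Mir223, exact binomial adjusted p = 0.138). The other lists lay inside: erythroid at 0.15, mural at 0.05, striated muscle at -0.22, liver and gut at -0.06, epithelial at 0.10, Hox-embedded at -0.33 and oligodendrocyte at 0.12. The Hox-embedded list was near the edge (percentile 3.99), with 4 detected members lower, 0 higher and 2 past the test. The erythroid share went from 0.0159% in replicate 1 to 0.00862% in replicate 2, although 2 of its members were higher and 1 lower. The mural and epithelial medians were below 0 with library totals, at -0.05 and -0.01.

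**Figure D4:**
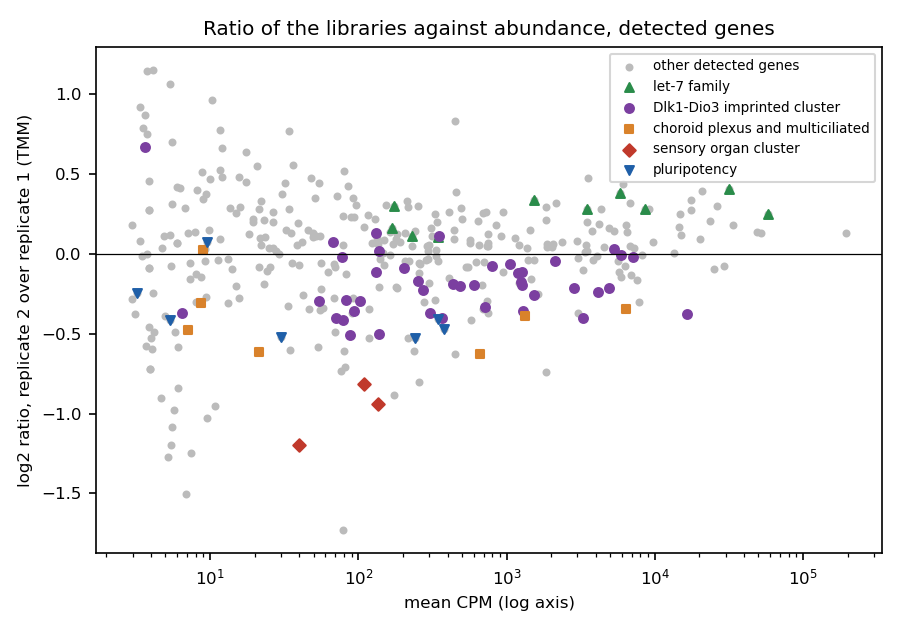
Log2 ratio of replicate 2 over replicate 1 after TMM normalization (y axis) against mean CPM (x axis, log scale) for the 377 detected genes, with markers for the let-7, Dlk1-Dio3, choroid plexus, sensory organ and pluripotency lists and grey points for other genes. The let-7 members lie above 0 (9 of 10 with library totals), and 3 of 3 sensory organ members lie below.

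Reads on the strand opposite to the annotated gene made up 2.16% of the counts on either strand in replicate 1 and 1.91% in replicate 2. Of 293 genes with at least 50 counts in each library, 265 had an opposite-strand share of 0, and 4 had a share over 1%, the highest being 3.33%. Nearly all opposite-strand counts, 99.7% in either library, fell on 12 genes.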

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

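Both tests of opposite-strand reads were chosen after the counts had been seen, as were the tests of read copies. A signal was looked for in the columns and summary rows outside the main measurement, where no control samples exist, against the limit that a count of 0 allows.

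Reads on the opposite strand numbered at least 50 in each library at 12 genes. The mean opposite-strand counts were 25148.5 at Gm24321, 19608.5 at Gm25927, 13063 at Gm25252, 10325.5 at Gm24083, 4544.5 at Gm25301, 3923 at Mir299b, 3566.5 at Gm25750, 1566 at Mir497b, 680.5 at Mir142b, 398.5 at Gm25641, 315.5 at Gm24111 and 88.5 at Mir203. Loss of strand during library preparation is argued against by the 25 most abundant genes, whose highest opposite-strand share was 0.00501%. In the later annotation 11 of the 12 lie opposite a microRNA gene on the other strand, against 21 of 1882 other genes (1.12%), which is consistent with reads of microRNA genes that the authors' annotation lacked. Mir203 has no such partner, and its reads stay open. No biological explanation was tested, since the design has 1 group.

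The partners of these genes were Mir409 (6235 ± 1679 opposite-strand reads relative to 1000000 gene counts), Mirlet7e (4888 ± 107), Mir376a (3249 ± 316), Mir191 (2576 ± 177), Mir378a (1134 ± 115), Mir299a (975 ± 136), Mir380 (887 ± 113), Mir497 (390 ± 11.5), Mir142 (170 ± 2.04), Mir9-1 (99.3 ± 0.400) and Mirlet7f-1 (78.8 ± 10.5). Counted on its own strand, the reads of Mir409 would rank 35 among the genes of the table.

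Multi-mapped reads were 40.6% of all reads in replicate 1 and 43.9% in replicate 2, more than were counted on genes. Their genes are not known from the tables. In the neural list the miR-124 genes and Mir9-2 (20 and 18 counts) had few counts, while Mir9-3 (3103 and 2823) and Mir125b-1 (8205 and 9013), which also have copies, did not. A candidate explanation for the low ones is that reads mapping to several copies are not assigned. It was tested on members of the other lists, where the median log2(CPM + 1) was 5.70 for 31 genes with a copy and 6.64 for 118 without, a difference that did not pass (two-sided permutation test, 100000 resamples, p = 0.282). The comparison cannot decide, since it mixes lists of unlike level. The 12 testis genes, for example, have no copy and had 0 counts in replicate 1 and 3 in replicate 2. If multi-mapped reads add no count, as was taken here, reads that fit several copies are missing from these genes by construction. How far this accounts for the low counts stays open, since the tables do not say which genes the multi-mapped reads fit.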

How the results depend on the processing

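The number of detected genes stayed within 1.5 times of the main value except with a floor of 1 count (602). Called genes numbered 2 with at least 50 counts in each library, where fewer genes were tested, and 1 with the edgeR exact test. The latter adds the spread estimated from these same libraries, so it is no independent check. The biological coefficient of variation ran from 14.02% to 15.7%. The rank correlation was 0.948 with no filter on low counts. No paired analysis was possible because there is 1 group.

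With all reads as the denominator the share of the 10 leading genes was 19.97%, and list shares were 4.19% (let-7), 1.24% (neural), 4.70% (Mir17), 2.56% (Dlk1-Dio3), 0.00470% (erythroid), 0.0114% (leukocyte), 0.663% (endothelial), 0.263% (mural), 0.00190% (striated muscle), 0.00804% (liver and gut), 0.0625% (epithelial), 0.0109% (sensory organ), 0.0141% (Hox-embedded), 0.0296% (oligodendrocyte), 0.0388% (pluripotency) and 0.321% (choroid plexus), by construction of the larger denominator.

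With Mir99a left out of the denominator they were 43.6% (10 leading genes), 13.7% (let-7), 4.06% (neural), 15.3% (Mir17), 8.34% (Dlk1-Dio3), 0.0371% (leukocyte), 2.17% (endothelial), 0.860% (mural), 0.00618% (striated muscle), 0.0263% (liver and gut), 0.204% (epithelial), 0.0967% (oligodendrocyte) and 1.04% (choroid plexus). List shares are higher by construction of the smaller denominator, and the share of the 10 leading genes is lower because Mir99a was the first of them.

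With genes that have a copy left out they were 57.2% (10 leading genes), 2.74% (neural), 12.9% (Mir17), 4.89% (Dlk1-Dio3), 0.747% (mural), 0.0161% (liver and gut), 0.179% (epithelial), 0.0198% (oligodendrocyte) and 0.0429% (pluripotency), and the range within clusters was 527-fold (Mir17), 13.3-fold (chromosome X) and 1976-fold (Dlk1-Dio3). Members with a copy leave the lists, while the 10 leading genes and the epithelial list have none and only the total is smaller. With reads on either strand the leukocyte share was 0.0293%, by construction of the larger total (4208561 and 3985056 counts). The neural share stayed above that of 12 lists under each alternative run.

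Without replicate 1 or 2 each share took the value of the other library. With 2 libraries such a value lies within 1 SD of the mean by construction, so it says nothing about stability. The widest relative range was that of the sensory organ list (0.0186% to 0.0382%), apart from the testis list at 0 and 3 counts. Depth limits genes near 10 counts, where 1 count is a large part of the value.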

Other observations

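The tests of explanations in this part were chosen, and their expected outcomes written down, after the results they bear on had been seen. The exact binomial test, the list ratios and the library totals quoted beside them had been planned beforehand. No biological explanation was tested against the technical ones, because the libraries are replicates of 1 group.

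MicroRNA genes in introns of Htr2c, the serotonin receptor gene expressed in choroid plexus, were present at 1832 ± 739 CPM for Mir1298, 173 ± 81.0 CPM for Mir448 and 76.1 ± 30.5 CPM for Mir1264. Mir1298 had 9696 counts in replicate 1 and 5121 in replicate 2, and Mir1912 had 30 and 9. These genes were in no list fixed beforehand and were noticed because they were lower in replicate 2.

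The median ratios of 6 lists lay outside the central 95% of matched random lists, above it for the let-7 and leukocyte lists and below it for the Dlk1-Dio3, sensory organ, pluripotency and choroid plexus lists. GC content was tested as a cause over the whole precursors. Across the 377 detected genes its Spearman correlation with the ratio was -0.00564. Removing a cubic GC trend moved no list median by more than 0.05 and left 6 of 6 lists outside. The list shifts thus did not follow the GC content of the precursors. The libraries were limited to RNA shorter than the precursors, and the GC content of the reads was not measured. The test therefore cannot decide on a GC bias of the reads, which stays open. More choroid plexus tissue in replicate 1 may account for the choroid part. The Htr2c genes had a median log2 ratio of -0.74, outside the range of matched lists (-0.39 to 0.31), but they were noticed for being low and so cannot count for it. A lower share of neural tissue in replicate 1 would make neural microRNAs higher in replicate 2. The neural list had a median of 0.01, with 9 detected members lower and 10 higher in replicate 2. In the exact binomial test 7 passed as lower and 2 as higher (11 and 1 with library totals, median -0.10). The sign of the list median depends on the scaling, and a small change in the main tissue would move its own share little. These values therefore cannot decide, and the explanation stays open. Leukocyte, endothelial and mural genes had a median of 0.30 against -0.39 for the choroid list. The difference passed an exact permutation test over genes (p = 0.0249). It did not pass over loci, where clustered genes count once (4 against 9 loci, exact permutation p = 0.0979). The choroid list had already been seen to be low in these same ratios, so neither p-value counts as evidence. In the mural list 3 detected members were lower and 3 higher in replicate 2.

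A further hypothesis was that the Dlk1-Dio3 shift covers the cluster as a whole, including members that the annotation lacked. The 4 members read on the opposite strand, Mir409, Mir376a, Mir299a and Mir380, had a median log2 ratio of -0.165, and 4 of 4 were below 0. Their ratios ran from -0.45 (Mir409) to -0.09 (Mir376a, exact 95% interval -0.13 to -0.06). With TMM, Mir127 (-0.01), Mir369 (-0.02) and Mir411 (0.03) were near 0, and 6 of the 42 detected members were higher in replicate 2, of which Mir411 passed the exact binomial test. With library totals these ratios were -0.12, -0.13 and -0.08, 3 members were higher with 0 past the test, and 35 were lower past it. Differences between members do not depend on the scaling, which moves all ratios alike. With TMM the exact 95% interval was -0.39 to -0.36 for Mir487b and -0.03 to 0.02 for Mir127. The members thus differed in size of shift beyond counting error, which is all that these intervals cover. Whether every member was lower in replicate 2 depends on the scaling and stays open.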
